A study of Mus musculus with 8 samples.

How the data were processed

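The series holds 8 samples of muscle stem cells, 4 H3K27ac libraries and 4 input libraries, and the labels assign each to FISC or ASC and to replicate 1 or 2. Per the labels' protocols, chromatin of sonicated nuclei was bound by antibody, tagmented while bound (ChIPmentation) and sequenced on a NextSeq 500 in single reads of 75 bases. Per the submitters' processing notes, the tools were bcl2fastq 2.19, BWA, Picard and MACS2, with the build mm10. Versions of the last 3, the settings of aligner and peak caller, the handling of duplicates and the part the inputs played in peak calling are not given in the sources used here. The inputs entered no test.

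The deposited files are 4 narrow peak lists, 1 for each H3K27ac library. The deposited fold enrichment is a ratio of reads at the summit to the local background, computed by the authors with MACS2. The deposited p and q columns are −log10 p and −log10 q values from the same caller. The deposited score is the integer part of 10 times the −log10 q in every peak. Because fold enrichment and q depend on each library's depth and background, fold was compared between libraries only where stronger enrichment is weighed. Otherwise what was compared is where peaks lie and how many bases they cover. No peak overlapped another within a list, so merging changed nothing (0 overlapping peaks). Only assembled chromosomes were used.

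Depth was estimated from the files. For each peak the fold enrichment and p-value were solved for a whole number of reads at the summit over a common background. Backgrounds of 2.33 reads in ASC replicate 1, 2.86 in ASC replicate 2, 2.72 in FISC replicate 1 and 2.82 in FISC replicate 2 fitted between 65.4 and 83.5% of 3000 sampled peaks within a tolerance of 0.01 in fold. Backgrounds were read as relative depth, an assumption that could not be checked without the settings of the peak caller.

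Gene positions came from RefSeq genes on GRCm38.p6, the assembly of mm10. The table used here gives gene start and end without strand or transcripts. For 21887 protein-coding genes the end with more covered bases within 2 kb, summed over all 4 libraries, stood for the start site. Of 10000 genes longer than 10 kb with a covered end, 81.8% had exactly 1 covered end. The choice sums covered bases over both conditions, and the ASC lists cover more, so ends covered in ASC weigh more. At some genes the choice takes the last exon. It also misses start sites away from both ends: windows of Ldha and Cox5a, enzymes of general metabolism, were covered in no library, so an uncovered window does not mark a silent gene. For 8445 genes no end was preferred, and 133 of these had a covered end. This departs from the plan, which asked for annotated start sites. The planned search of 27 motifs and the 5'-most start site need sequence or strand and were not run here.

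The tests, the lists, the naming rule and the alternatives were fixed before the data were examined, except where the text says otherwise. Library totals, shares and Jaccard indices were compared with exact 2-sided permutation tests. Regions were the union of the 4 lists (overlap of at least 1 base), and they were counted for the 2 other pairings of the libraries as well. Window breadth was the kb under peaks within 2 kb of the chosen end. Distal breadth was the kb under peaks more than 2 kb from every chosen end, within 50 kb of the gene's own and nearest to it. Genes covered in at least 2 libraries were fitted with limma (eBayes with trend) on the linear scale, without scaling, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Gene lists were tested with camera (preset correlation 0.01), with camera on an estimated correlation and with fry. With 2 libraries per condition, the estimated correlation leaves camera few degrees of freedom, and it called no list as covered. A call lost there therefore decides little for any list.

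The 23 lists comprised 15 of the studied cells (satellite cell identity, quiescence, Notch pathway, myogenic commitment and sarcomere, cell cycle, immediate early, heat shock, ribosome biogenesis, glycolysis, oxidative phosphorylation, extracellular matrix, inflammatory mediators, interferon response, H3K27 enzymes and readers, Hox genes) and 8 of other cell types (fibro-adipogenic and fibroblast, endothelial, myeloid, lymphoid, smooth muscle and pericyte, Schwann and tendon, liver, neuron). They held 439 members, of which 437 matched the annotation, 432 different genes. Genes named are the 10 largest called differences in each direction for each breadth measure, 2 to 4 members of each list in order of absolute difference, and Pax7, Myf5, Myod1, Myog, Cdkn1c, Calcr, Hey1 and Spry1. Predicted genes and clone names were left out.

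Alternatives were stricter peak cut-offs (−log10 q of at least 5, fold enrichment of at least 5), lists cut to equal number, windows of 1 and 5 kb, distal limits of 20 and 100 kb, another overlap rule, peaks joined within 500 bases, start sites of all gene types, division by total covered length, a log scale (100 bases added), a looser filter, no trend, a replicate block, and each library left out. Lists cut to equal covered length, both gene ends, unshared windows, scaling with the block, and 28 gene families were added after the data were seen. Replicate numbers did not pair the libraries: residual correlation within numbers was −0.0080 for windows and 0.0055 for distal territory, so the unblocked fit was kept.

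In a self-test, 200 genes were shifted in each of 20 runs on normal data simulated with the moderated variances of the fit. Shifts up and down were balanced, values had no bounds, and libraries did not differ in list length. False calls in the real fits may therefore differ from the rates given here. Shifts of 0.5 and 1 kb in windows were called in 7.4 and 89.7% of cases, with 6.8% false calls among all calls. Distal shifts of 1 and 3 kb were called in 12.0 and 80.1%, with 3.9% false calls. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.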

Results

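H3K27ac, the acetylated form of histone H3 found at active promoters and enhancers, was mapped in muscle stem cells (satellite cells) from skeletal muscle of C57BL/6 mice. Freshly isolated satellite cells (FISC) came from muscle that received no treatment, and activated satellite cells (ASC) came from muscle 2.5 days after injury with barium chloride. Each condition had 2 H3K27ac libraries, and the deposited MACS2 peak list of each library (genome build mm10) was analysed. The question behind the series is how acetylation round transcription start sites and in distal intergenic regions changes on activation. Values per condition are the mean ± SD of the libraries (n = 2), in the order ASC against FISC. The labels do not say whether the replicates were separate animals. P-values of the permutation tests and of the fits per gene therefore measure only the spread between these samples, which may be technical. Those of camera at the preset correlation compare listed genes with other genes, so they rest on the spread between genes and not between libraries. With 2 libraries against 2, the smallest possible 2-sided exact p is 0.333.

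Acetylated regions were longer and more numerous in ASC. Peaks covered 53.4 ± 6.03 Mb of the genome in ASC and 34.0 ± 0.44 Mb in FISC, a ratio of 1.57. A library held 52427 ± 3215 peaks in ASC and 44053 ± 1359 in FISC. The median peak was 609 ± 8.49 bases wide in ASC and 506 ± 12.7 in FISC, and peaks longer than 5 kb numbered 514 ± 187 against 100.5 ± 4.95. For each of these measures both ASC libraries lay above both FISC libraries (exact 2-sided permutation p = 0.333). Read depth was estimated from the deposited fold enrichments and p-values, which gave background levels of 2.59 ± 0.378 reads in ASC and 2.77 ± 0.0725 in FISC on average. Library by library, ASC replicate 2 had both the longest list (57.7 Mb) and the highest background (2.86 reads), and ASC replicate 1 had the lowest background (2.33 reads).

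**Figure D1:**
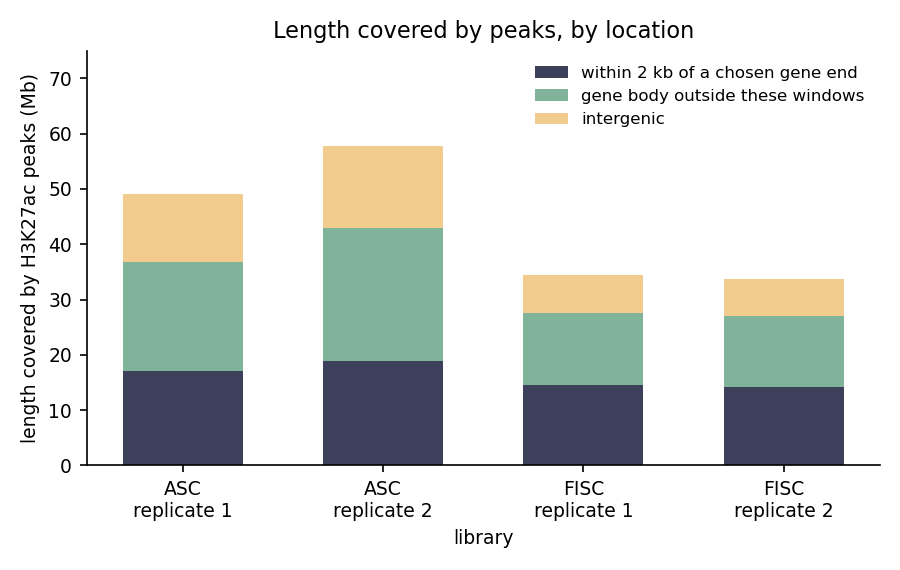
Bases under H3K27ac peaks in each library, in megabases, stacked by place: within 2 kb of a gene end used as start site, elsewhere in gene bodies, and intergenic. Intergenic length was 13.6 ± 1.76 Mb in ASC and 6.73 ± 0.00501 Mb in FISC.

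Covered length gained most in proportion between genes and most in megabases in gene bodies, where it rose by 8.91 Mb. Intergenic covered length was 13.6 ± 1.76 Mb in ASC and 6.73 ± 0.00501 Mb in FISC (ratio 2.01), gene bodies outside start-site windows held 21.9 ± 3.09 against 13.0 ± 0.222 Mb (1.69), and windows held 18.0 ± 1.19 against 14.3 ± 0.213 Mb (1.25). A window is the 2 kb on each side of a gene end. The annotation used here has no strand, so the end with more covered bases over all 4 libraries stood for the start site. Windows made up 33.7 ± 1.59% of covered length in ASC and 42.1 ± 0.0823% in FISC, while intergenic regions made up 25.4 ± 0.421% and 19.8 ± 0.241%. Of all peaks, 24.4 ± 1.43% against 30.3 ± 0.465% lay in windows and 30.1 ± 0.304% against 24.5 ± 0.0388% were intergenic. Each of these shares separated the conditions (exact 2-sided permutation p = 0.333). They rest on the lists as deposited: when each list was cut to its strongest peaks at equal covered length, the window share of length became 3.68 points higher in ASC, the window share of peaks 20.9 points higher, and the ASC minus FISC difference in the intergenic share of peaks went from +5.63 to −4.73 points. The intergenic share of length, 5.58 points higher in ASC as deposited, was 0.43 points higher there and no longer separated the conditions (exact 2-sided permutation p = 0.667). Lists cut to equal peak number kept the directions, with −3.32 points for the window share of peaks and +5.18 points for the intergenic one. Body shares of peaks as deposited were alike, 45.5 ± 1.12% and 45.2 ± 0.504%.

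**Figure D2:**
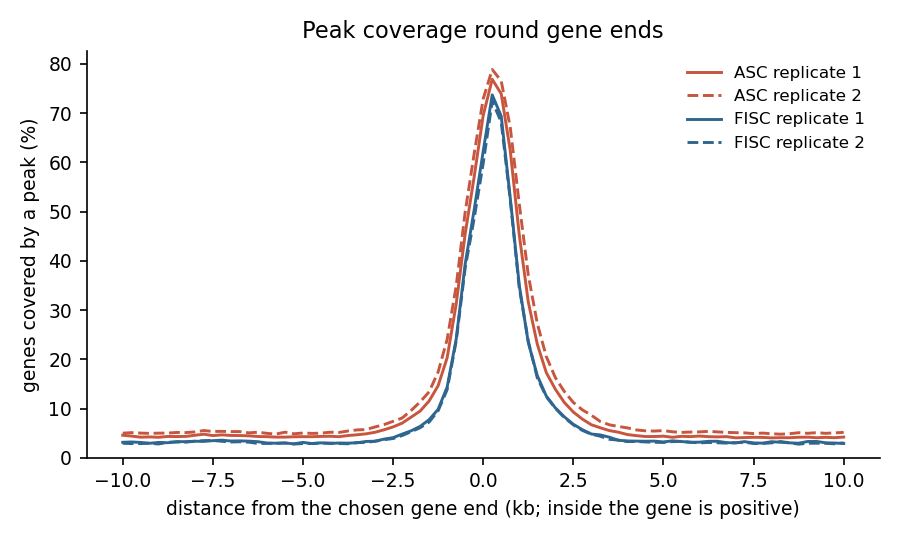
Percent of 13442 protein-coding genes with a covered end (vertical axis) that had a peak at each distance from that end in kb (horizontal axis; negative values lie outside the gene), 1 line per library. At 0.25 kb inside the gene the lines lay between 72.4 and 78.9%, and at 5 kb between 3.12 and 5.53%.

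Round the chosen gene ends, the conditions differed more at 1 kb inside the gene than at 0.25 kb. At 0.25 kb inside the gene, 76.9 and 78.9% of genes were covered in the ASC libraries and 73.7 and 72.4% in the FISC libraries. At 1 kb the values were 45.3 and 51.6% against 35.1 and 34.5%, and at 5 kb they were 4.40 and 5.53% against 3.22 and 3.12%. At 10 kb outside the gene they were 4.59 and 5.01% against 3.15 and 2.96%, so 5 kb lay at the level found far from the ends. The genes were the 13442 with a covered end.

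The same places were acetylated in libraries of the same condition far more than across conditions. The Jaccard index of covered bases was 0.711 between the ASC libraries and 0.643 between the FISC libraries, and between 0.396 and 0.406 for the 4 mixed pairs (exact permutation p = 0.333 over the 3 ways of pairing). The lists merged into 72585 regions, of which 19493 had a peak in all 4 libraries and 26942 in a single library. Regions seen in both ASC libraries and neither FISC library numbered 14455, and regions seen in both FISC libraries and neither ASC library numbered 5301. The other pairings of the libraries gave 209 and 550 regions by replicate number and 164 and 645 crossed. They show what a split other than by condition gives, not how far replicates disagree. That disagreement was larger: of ASC peaks, 88.2% in replicate 1 and 73.5% in replicate 2 touched a peak of the other replicate. For FISC the values were 75.6 and 78.7%. With a condition held by a lone library the counts of condition-specific regions rise. They were 26950 ASC regions without ASC replicate 1, 23571 without ASC replicate 2, 11567 FISC regions without FISC replicate 1 and 13073 without FISC replicate 2. Lists cut to equal peak number, as planned, gave 11376 regions for ASC and 6110 for FISC, the ASC lists still covering 16.9 Mb more. At equal covered length the counts were 1583 for ASC and 13080 for FISC. The split between the directions therefore depends on the covered length of the lists.

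Condition-specific regions lay mostly away from start sites in both directions, as did regions seen in a single library (8.24% in windows, 59.0% in bodies and 32.8% intergenic). Of ASC-specific regions 42.3% were intergenic (95% Wilson interval 41.5 to 43.1%), 50.6% (49.8 to 51.5%) lay in gene bodies and 7.04% (6.63 to 7.46%) in windows. FISC-specific regions were 35.4% intergenic (34.2 to 36.7%), 57.7% (56.4 to 59.0%) in bodies and 6.87% (6.22 to 7.58%) in windows. Regions shared by all 4 libraries fell in windows in 51.6% (50.9 to 52.3%). These intervals cover counting error only. ASC-specific intergenic regions had a median width of 699 bases and FISC-specific ones 588.

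At individual start sites, the 10 largest gains were as follows. The window of Tk1, the thymidine kinase of S phase (chr11:117815519–117826087), was fully covered in ASC and uncovered in FISC (4.0 ± 0 against 0 ± 0 kb, adjusted p = 0.00175, of a window of 4 kb). Rrm2, a subunit of ribonucleotide reductase (3.95 ± 0.0665 against 0.46 ± 0.0198 kb), and Hmga2, a chromatin protein of growing cells (chr10:120361268–120476469; 3.84 ± 0.0792 against 0.10 ± 0.141 kb), also rose. The giant sarcomere gene Ttn (chr2:76703980–76982557) had 3.62 ± 0.129 against 0 ± 0 kb. Gains of like size were seen at Arhgap22, a regulator of small GTPases (chr14:33213994–33369936; 4.0 ± 0 against 0 ± 0 kb), Traf1, an adaptor of tumour necrosis factor receptors (3.94 ± 0.0785 against 0 ± 0 kb), and the nucleotidase gene Nt5c2 (3.94 ± 0.0912 against 0.117 ± 0.166 kb), whose chosen end may be its last exon. Afmid, an enzyme of tryptophan breakdown, had 3.9 ± 0.141 against 0 ± 0 kb in a window that overlaps that of Tk1. The cilium-related genes Spef1l (3.67 ± 0.0509 against 0 ± 0 kb) and Fbf1 (3.48 ± 0.542 against 0 ± 0 kb) completed the 10 largest gains. Limma adjusted p-values of the 10 lay between 0.00175 and 0.00308. The other end of Fbf1 was covered in both conditions (1.86 against 1.0 kb), so its chosen end may not be its start site.

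The 10 largest losses in windows were led by Hmcn2 and Gpx3. Hmcn2, a hemicentin of the basement membrane (chr2:31314255–31460738), fell (0.463 ± 0.0651 against 3.37 ± 0.562 kb, adjusted p = 0.00444), as did the secreted glutathione peroxidase gene Gpx3 (chr11:54902854–54910387; 0.657 ± 0.392 against 3.51 ± 0.123 kb). Serping1, a complement inhibitor, lost all coverage (0 ± 0 against 2.49 ± 0.0573 kb, adjusted p = 0.0018). Losses also covered the tenascin gene Tnxb (0.117 ± 0.165 against 2.62 ± 0.253 kb), the sphingosine phosphate receptor gene S1pr3 (0.436 ± 0.226 against 2.99 ± 0 kb), the semaphorin gene Sema3b (0.606 ± 0.303 against 2.98 ± 0.257 kb), the RNA-binding Csdc2 (0.349 ± 0.087 against 2.97 ± 0.259 kb) and the chromatin remodelling subunit Dpf1 (0.204 ± 0.289 against 2.66 ± 0.0424 kb), whose other end moved the opposite way (0.938 kb in ASC and 0.409 in FISC). The receptor gene Mrgprf (0.579 ± 0.819 against 2.95 ± 0.181 kb, adjusted p = 0.0156) and the corepressor gene Hr (1.35 ± 1.05 against 3.68 ± 0.0573 kb, adjusted p = 0.0273) were less secure. Their calls were lost without FISC replicate 1 (limma adjusted p = 0.0764 and 0.118) and without FISC replicate 2 (0.0967 and 0.134).

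Across 12905 genes with a covered window, 3360 rose in ASC and 456 fell at adjusted p 0.05. The median of all genes was +0.279 kb, and it became −0.352 kb when covered lengths were divided by each library's total, so gains and losses are best read against that median. On that scale 1114 genes rose and 5073 fell, which moved the share of rises among calls from 88.1 to 18.0%. Of the rises 1067 held on both scales and 155 reversed to a fall. All 456 falls held, but division by the total can only deepen a fall. That division also turns wide windows of like breadth in both conditions into falls. At equal covered length 2041 genes rose and 1528 fell. Of the 3360 rises as covered, 1997 held there and 63 reversed to a fall, and 412 of the 456 falls held. In 72.6% of genes the 2 conditions did not overlap (8006 higher and 1367 lower in ASC). For 1 gene with exchangeable libraries the probability is 33.3%. All genes share the same 4 libraries, and each ASC list is longer than each FISC list, so list length enters the share of 72.6%. Leaving out a library gave 3256 rises and 253 falls without ASC replicate 1, 1691 and 334 without ASC replicate 2, 981 and 65 without FISC replicate 1, and 841 and 55 without FISC replicate 2.

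Of 8 regulators of satellite cells and myogenesis chosen beforehand, Calcr alone passed the test at its start site as covered, and more passed on other scales or with the replicate block. Windows of Pax7, the master regulator of satellite cells (chr4:139737059–139833530), had 2.84 ± 0.00778 against 3.17 ± 0.129 kb, adjusted p = 0.0831. The myogenic factors Myf5 (3.94 ± 0.0799 against 4.0 ± 0 kb, adjusted p = 0.611) and Myod1 (3.22 ± 0.27 against 3.23 ± 0.117 kb, adjusted p = 0.951) did not pass. After division by total covered length Pax7 (−1.74 kb, limma adjusted p = 0.00372), Myf5 (−1.89 kb, 0.00699), Myod1 (−1.51 kb, 0.00473), Hey1 (−2.10 kb, 0.00208) and Spry1 (−1.25 kb, 0.0143) passed as falls. Hey1 did so at equal covered length too (−1.12 kb, 0.0251). There Pax7 (−0.335 kb, 0.0828), Myf5 (−0.0565 kb, 0.609), Myod1 (+0.1665 kb, 0.495) and Spry1 (−0.8065 kb, 0.479) did not pass. Division by the total turns a wide window of like breadth in both conditions into a fall. The scaled values of Myf5 and Myod1, alike as covered, therefore show no loss of their own. Myog, which drives differentiation, had 0.685 ± 0.687 against 0 ± 0 kb, adjusted p = 0.161. Spry1, a brake on growth factor signalling, had 3.69 ± 0.184 against 3.34 ± 0.281 kb, adjusted p = 0.177, a rise in value that reversed after division by total length. The Notch target Hey1 had 2.6 ± 0.379 against 3.29 ± 0.167 kb, adjusted p = 0.0667, and passed with the replicate block (limma adjusted p = 0.0278). The cell cycle inhibitor Cdkn1c had 0.234 ± 0.33 against 0.382 ± 0.54 kb, adjusted p = 0.725. Calcr, the calcitonin receptor that holds cells in quiescence, lost its coverage (0 ± 0 against 1.13 ± 0.26 kb, adjusted p = 0.00836).

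**Figure D3:**
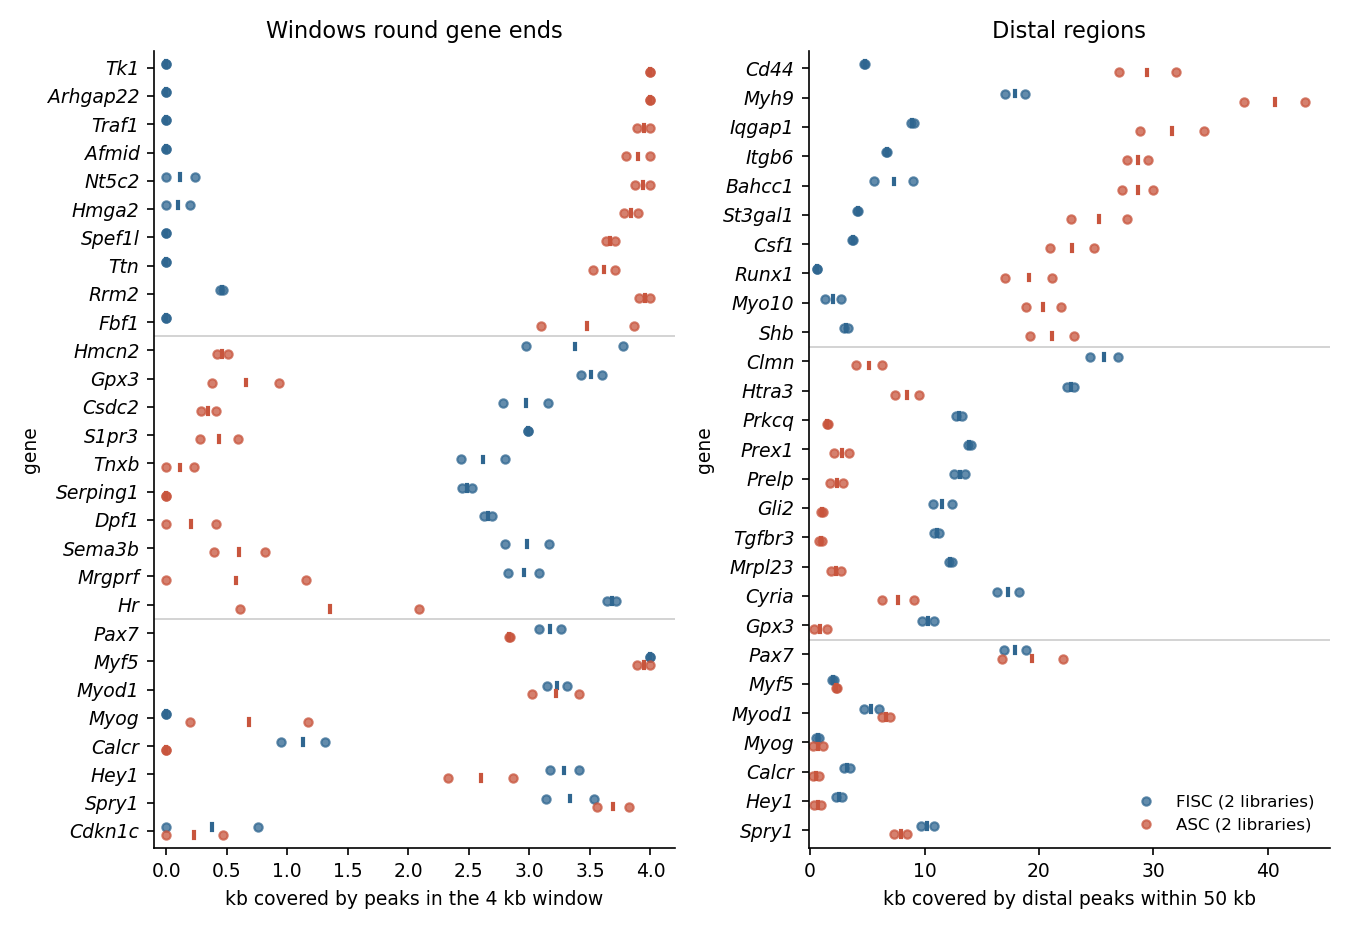
Covered kb per gene in start-site windows (left) and in distal territory (right) for the 10 largest gains, the 10 largest losses and the fixed satellite cell regulators; each dot is a library and each tick a condition mean. For Pax7 windows both ASC libraries lay below both FISC libraries, and Calcr was uncovered in both ASC libraries.

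Among the fixed lists, cell cycle genes had the largest mean gain in windows, as covered and when scaled. In the cell cycle list 25 rose and 0 fell of 29 (26 and 0 adjusted over the list alone, 18 and 2 scaled; adjusted p = 2.5e-07), with a mean of 2.27 kb per gene in ASC and 0.923 in FISC. The call was lost at adjusted p = 0.608 with an estimated correlation. Here and below, the first counts are adjusted over all genes, the next are adjusted over the list alone, the next come after division by total covered length ("scaled"), and the p-value is that of limma camera against all other genes. E2f2, a factor for S-phase entry (2.83 ± 0.0933 against 0.691 ± 0.136 kb), and Mcm6, a subunit of the replicative helicase (2.59 ± 0.0283 against 0.609 ± 0.21 kb), rose. In the list of myogenic commitment and sarcomere genes 11 rose and 0 fell of 21 (12 and 1 adjusted over the list alone, 11 and 7 scaled; adjusted p = 0.0783). The fetal acetylcholine receptor subunit Chrng (2.22 ± 0.292 against 0 ± 0 kb), the troponin gene Tnnt3 (2.17 ± 0.205 against 0.0305 ± 0.0431 kb) and the receptor subunit Chrna1 (3.57 ± 0.158 against 1.59 ± 0.0955 kb) rose. Scaled, camera placed the myogenic list above other genes (adjusted p = 2.7e-06; 0.474 with an estimated correlation), but not at equal covered length (0.937; 3 rises and 1 fall of 13).

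Quiescence genes were placed below other genes, and so did genes of smooth muscle and pericytes, given below. In the quiescence list 3 rose and 6 fell of 23 (3 and 6 adjusted over the list alone, 1 and 18 scaled; adjusted p = 3.8e-04), with means of 2.22 and 2.32 kb and an adjusted p = 0.608 with an estimated correlation. Lists of equal covered length kept the call (camera adjusted p = 0.0296; 0.652 with an estimated correlation). The list was set below other genes and did not fall by itself: over all members it had 2.13 ± 0.167 kb in ASC and 2.23 ± 0.0842 in FISC, and 0 lists were called lower by fry. The Notch target Heyl (1.39 ± 0.324 against 2.72 ± 0.179 kb) and the stress-response gene Ndrg2 (1.68 ± 0.0544 against 2.6 ± 0.176 kb) fell, while Angpt1, a ligand of the Tek receptor, rose (2.2 ± 0.23 against 0.378 ± 0.0651 kb). For the Notch pathway 1 rose and 1 fell of 14 (0 and 1 adjusted over the list alone, 0 and 8 scaled; adjusted p = 0.332). Its modifier Lfng had 1.28 ± 0.521 against 0.52 ± 0.145 kb, adjusted p = 0.0873. For satellite cell identity 6 rose and 2 fell of 16 (6 and 2 adjusted over the list alone, 2 and 8 scaled; adjusted p = 0.882). The integrin gene Itga7 (4.0 ± 0 against 1.67 ± 0.113 kb) and the growth factor receptor genes Fgfr4 (3.81 ± 0.27 against 1.49 ± 0.512 kb) and Met (3.96 ± 0.0622 against 2.11 ± 0.173 kb) rose, the other end of Fgfr4 being lower in value in ASC (2.09 against 2.28 kb), and the secreted chordin-like gene Chrdl2 fell (0.424 ± 0.18 against 1.96 ± 0.714 kb, adjusted p = 0.0333). The calls for Heyl (0.0636 and 0.0900) and Ndrg2 (0.0933 and 0.0660) were lost without FISC replicate 1 or 2, and that for Chrdl2 without ASC replicate 2 (0.0719) or FISC replicate 2 (0.0563; limma adjusted p each). With an estimated correlation no list was called in windows (0 lists, camera).

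Growth, stress and metabolic lists were not set apart from other genes in windows. In the immediate early list 4 rose and 0 fell of 25 (3 and 0 adjusted over the list alone, 0 and 19 scaled; adjusted p = 0.895), and when scaled camera placed the list below other genes (adjusted p = 0.00837; 0.739 with an estimated correlation). Fosl1, an AP-1 subunit, rose (3.95 ± 0.075 against 2.16 ± 0.0219 kb), and Ier3, a survival factor, had 3.06 ± 0.432 against 2.29 ± 0.0205 kb, adjusted p = 0.0577. For heat shock genes 5 rose and 0 fell of 12 (5 and 0 adjusted over the list alone, 0 and 5 scaled; adjusted p = 0.349). The neighbouring mitochondrial chaperone genes Hspe1 (3.93 ± 0.0509 against 2.73 ± 0.0933 kb) and Hspd1 (3.86 ± 0.0099 against 2.73 ± 0.0933 kb) rose as covered and reversed when scaled. For ribosome biogenesis 6 rose and 0 fell of 20 (8 and 0 adjusted over the list alone, 0 and 9 scaled; adjusted p = 0.303). The nucleolar genes Nop58 (2.49 ± 0.0332 against 1.44 ± 0.272 kb) and Rrs1 (2.51 ± 0.409 against 1.47 ± 0.0735 kb) rose, Rrs1 reversing at equal covered length. Their calls were lost without FISC replicate 2 (limma adjusted p = 0.0839 and 0.148), that of Rrs1 also without FISC replicate 1 (0.12). For glycolysis 9 rose and 0 fell of 16 (11 and 0 adjusted over the list alone, 1 and 4 scaled; adjusted p = 0.251). The enzyme genes Pgk1 (3.95 ± 0.0735 against 1.32 ± 0.266 kb) and Eno1 (4.0 ± 0 against 2.83 ± 0.0318 kb) rose, Eno1 reversing when scaled. For oxidative phosphorylation 5 rose and 0 fell of 19 (0 and 0 adjusted over the list alone, 0 and 3 scaled; adjusted p = 0.242). The respiratory chain genes Sdhb and Uqcrfs1 had 1.93 ± 0.479 against 1.01 ± 0.276 kb, adjusted p = 0.0626, and 2.44 ± 0.228 against 1.64 ± 0.376 kb, adjusted p = 0.0576.

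Matrix, inflammatory and developmental lists were mixed. For extracellular matrix 9 rose and 4 fell of 28 (10 and 7 adjusted over the list alone, 5 and 15 scaled; adjusted p = 0.192). The protease inhibitor gene Timp1 (2.99 ± 0.0361 against 0.103 ± 0.146 kb) and the collagen gene Col8a1 (2.87 ± 0.0559 against 0.831 ± 0.181 kb) rose. For inflammatory mediators 7 rose and 1 fell of 16 (9 and 1 adjusted over the list alone, 5 and 3 scaled; adjusted p = 0.332). The chemokine genes Ccl2 (2.56 ± 0.0226 against 0.206 ± 0.0297 kb) and Cxcl2 (1.4 ± 0.213 against 0 ± 0 kb) rose, and camera called this list higher when scaled (adjusted p = 0.0209; 0.474 with an estimated correlation). For the interferon response 3 rose and 2 fell of 17 (3 and 2 adjusted over the list alone, 1 and 6 scaled; adjusted p = 0.242). The antiviral gene Rsad2 (2.57 ± 0.0849 against 0.877 ± 0.237 kb) and the factor Irf1 (2.17 ± 0.0481 against 1.35 ± 0.181 kb) rose. For writers, erasers and readers of H3K27 marks 3 rose and 0 fell of 17 (2 and 0 adjusted over the list alone, 0 and 9 scaled; adjusted p = 0.895). The Polycomb genes Suz12 (2.54 ± 0.235 against 1.68 ± 0.0898 kb) and Eed (2.73 ± 0.0431 against 1.92 ± 0.012 kb) rose as covered and reversed when scaled. For Hox genes 7 rose and 2 fell of 17 (9 and 3 adjusted over the list alone, 3 and 9 scaled; adjusted p = 0.895). There were rises at members of the list such as Hoxa11 (2.72 ± 0.56 against 0.36 ± 0.209 kb). The calls for Irf1, Suz12, Eed and Hoxa11 were lost without FISC replicate 1 (limma adjusted p = 0.0688, 0.0986, 0.0724 and 0.0594) and without FISC replicate 2 (0.12, 0.129, 0.0774 and 0.0526). Scaled mean differences were negative for every list of the studied cells except cell cycle (+0.681 kb), myogenic (+0.382 kb) and inflammatory genes (+0.0278 kb).

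**Figure D4:**
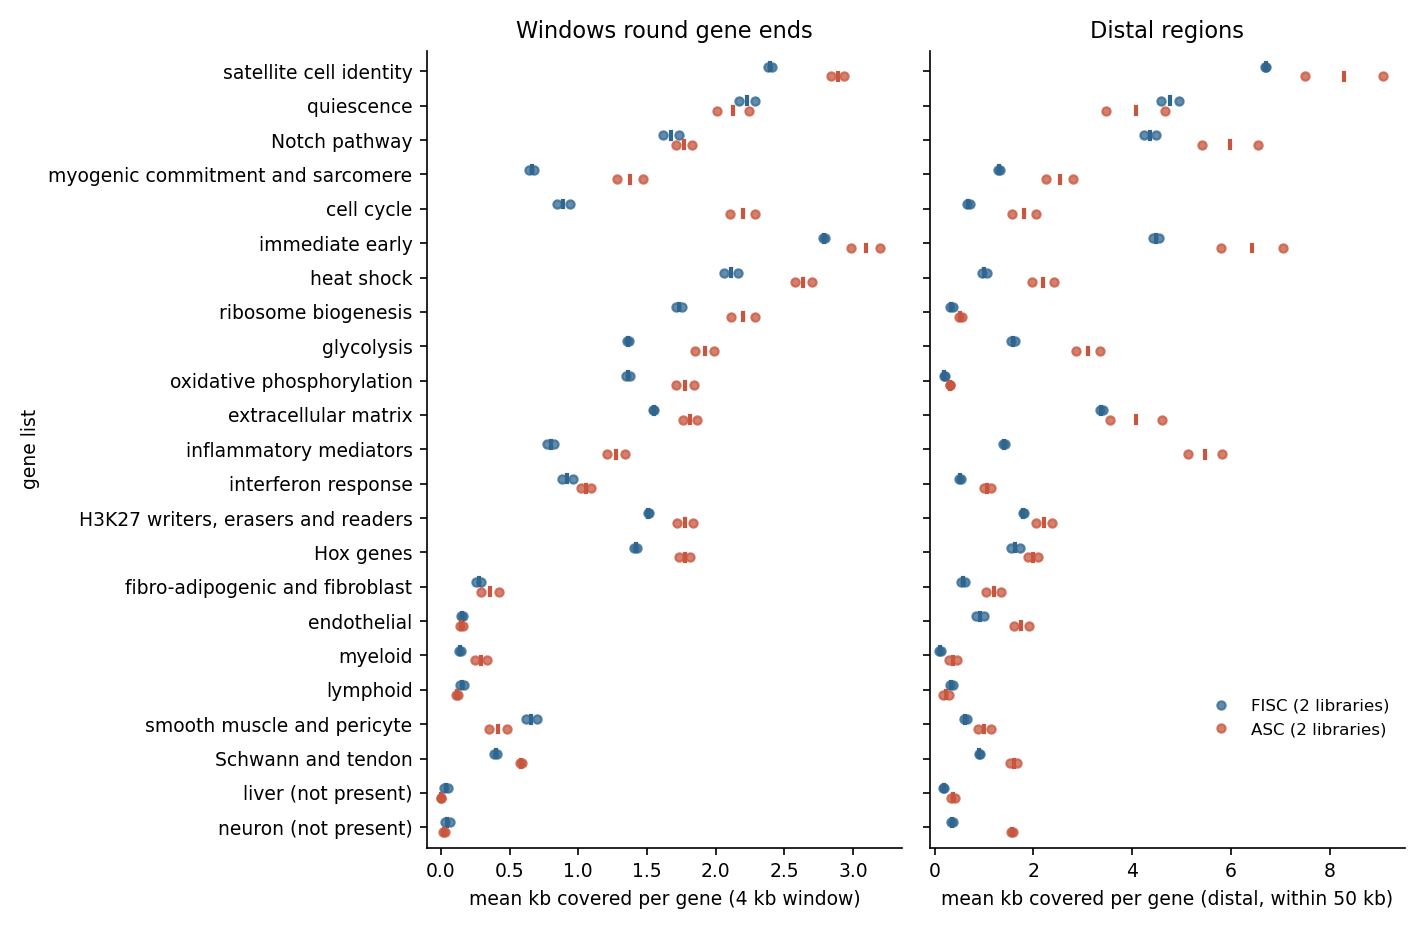
Mean covered kb per member of the 23 gene lists, in start-site windows and in distal territory, with a dot for each library and colour by condition. Means are over all members, uncovered ones counted as 0: cell cycle windows had 0.892 kb in FISC and 2.2 kb in ASC, and distal territory of inflammatory genes 1.4 and 5.48 kb.

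Lists of other cell types were tested for what the sorted cells carried along. Genes of smooth muscle and pericytes lay below other genes in windows: 0 rose and 4 fell of 6 (0 and 4 adjusted over the list alone, 0 and 6 scaled; adjusted p = 4.5e-06), with means of 0.807 and 1.3 kb and an adjusted p = 0.608 with an estimated correlation. The actin-binding gene Tagln (0.195 ± 0.276 against 1.13 ± 0.141 kb), the growth factor receptor gene Pdgfrb (0.138 ± 0.194 against 0.912 ± 0.0233 kb), the channel subunit Abcc9 (0 ± 0 against 0.51 ± 0.0948 kb) and the proteoglycan gene Cspg4 (0.10 ± 0.141 against 0.607 ± 0.0198 kb) fell. Those calls were fragile: limma adjusted p was 0.102 for Tagln and 0.0838 for Pdgfrb without FISC replicate 1 and 0.0805 and 0.0978 without FISC replicate 2. Abcc9 had 0.0739 without ASC replicate 1 and 0.0990 without ASC replicate 2, and Cspg4 lost its call whichever library was left out (0.104 and 0.0568 without ASC replicate 1 and 2, 0.132 and 0.156 without FISC replicate 1 and 2).

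For fibro-adipogenic and fibroblast genes 2 rose and 1 fell of 8 (2 and 1 adjusted over the list alone, 1 and 2 scaled; adjusted p = 0.251). The surface gene Ly6a rose (1.8 ± 0.513 against 0 ± 0 kb) and the matrix gene Dpt fell (1.01 ± 0.354 against 2.32 ± 0.0757 kb). For endothelial genes 1 rose and 0 fell of 3 (1 and 1 adjusted over the list alone, 1 and 2 scaled; adjusted p = 0.332), a list whose mean and median differed in sign, with the coreceptor Eng rising (0.879 ± 0.103 against 0 ± 0 kb; 0.245 against 0.536 kb at its other end) and the receptor Tek at 0.792 ± 0.252 against 1.35 ± 0.0354 kb, adjusted p = 0.0519. Without FISC replicate 1 or 2 the calls for Ly6a (0.0660 and 0.0715), Dpt (0.0780 and 0.0760) and Eng (0.0527 and 0.0565) were lost (limma adjusted p). For Schwann and tendon genes 2 rose and 1 fell of 4 (3 and 1 adjusted over the list alone, 1 and 1 scaled; adjusted p = 0.87). The neurotrophin receptor Ngfr rose (1.92 ± 0.0863 against 0.379 ± 0.222 kb; 0.395 against 0.769 kb at its other end), and the tendon factor Scx rose (3.3 ± 0.115 against 2.25 ± 0.0177 kb) but reversed when scaled. Of 22 myeloid windows, those of Spi1, Cd68, Cd14 and Fcgr3 were covered in all 4 libraries, those of Csf1r (0.347 kb in ASC replicate 2) and Laptm5 (0.32 kb in ASC replicate 1) in a single ASC library, and the other 16 in none. Of the tested genes 1 rose and 0 fell of 4 (1 and 0 adjusted over the list alone, 0 and 0 scaled; adjusted p = 0.332). Scaled, camera placed these above other genes (adjusted p = 0.0402; 0.474 with an estimated correlation), though none of the 4 was called on that scale. The lipopolysaccharide coreceptor Cd14 rose (1.47 ± 0.0106 against 0.645 ± 0.0834 kb), a call lost without FISC replicate 1 (limma adjusted p = 0.0634) and 2 (0.0531). Scaled mean differences were negative for every other cell type list tested except the myeloid (+0.286 kb). Cd68 had 2.49 ± 0.874 against 1.2 ± 0.216 kb, adjusted p = 0.0777, Fcgr3 0.94 ± 0.548 against 0.327 ± 0.164 kb, adjusted p = 0.147, and the factor Spi1 1.23 ± 0.146 against 0.818 ± 0.192 kb, adjusted p = 0.0925, reversing at equal covered length.

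Some window calls for named genes depended on scale without turning. Of 61 calls as covered, 12 were lost after division by total covered length: the 6 whose sign turned (Hspe1, Hspd1, Eno1, Suz12, Eed and Scx), and Met (+0.55 kb, limma adjusted p = 0.104), Fosl1 (+0.478 kb, 0.116), Nop58 (+0.209 kb, 0.443), Rrs1 (+0.157 kb, 0.409), Irf1 (+0.0568 kb, 0.801) and Cd14 (+0.379 kb, 0.0616). Lists of equal covered length lost 5, at Col8a1 (+0.0155 kb, 0.988), Ngfr (+0.423 kb, 0.609), Rrs1 (−0.0045 kb, 0.981), Chrdl2 (−1.81 kb, 0.0614) and Ndrg2 (−1.88 kb, 0.0706). Chrng, Cxcl2, Ly6a and Eng had too little coverage there to be tested. The direction also depended on the gene end chosen: at 5 of the 61 (Tk1, Dpf1, Fgfr4, Eng and Ngfr) the means of the other end differed in the opposite direction, untested there.

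Lymphoid, liver and neuron lists each had fewer than 3 windows covered in at least 2 libraries, so no set test was run on them. Both FISC libraries covered 2 of 12 lymphoid, 1 of 12 liver and 1 of 12 neuronal windows, and both ASC libraries covered 1, 0 and 1. Cd4 fell (0.116 ± 0.164 against 0.599 ± 0.0686 kb, adjusted p = 0.0348), a call lost without ASC replicate 2 (limma adjusted p = 0.173), FISC replicate 1 (0.186) or FISC replicate 2 (0.15). The B-cell receptor gene Cd79a had 1.08 ± 0.0544 against 1.25 ± 0.118 kb, adjusted p = 0.325, and the synapsin gene Syn1 0.293 ± 0.117 against 0.573 ± 0.263 kb, adjusted p = 0.216.

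Windows covered in both libraries of a condition and in neither of the other numbered 603 for ASC and 233 for FISC. The other pairings gave 26 and 26 by replicate number and 14 and 51 crossed, and 11381 of 21887 protein-coding genes were covered in all 4 libraries. At equal covered length they were 126 for ASC and 1675 for FISC. FISC-specific genes became 398 without ASC replicate 2, 366 without FISC replicate 1 and 477 without FISC replicate 2. Among myogenic genes 10 were ASC-specific (Myog, Mymk, Myh3, Tnnt2, Tnni1, Chrng, Ttn, Myl1, Lmod3 and Mybph) and 0 were FISC-specific. ASC-specific cell cycle genes were Ccnb1, Cdc6, Bub1 and Aurkb, and ASC-specific inflammatory genes were Cxcl2, Il6, Il1b, Il33 and Icam1. FISC-specific members were Calcr, the matrix genes Col15a1, Lama4, Bgn and Mmp2, and the interferon targets Ifit1 and Ifit3. Some genes outside the lists were chosen after their values were seen: the caveolar muscle gene Cavin4 (3.05 ± 0.106 kb in ASC), and on the FISC side the titin-capping gene Tcap (1.75 ± 0.146 kb) and the lipid carrier Apoe (1.75 ± 0.178 kb).

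In distal territory, the 10 longest gains were led by Cd44 and Myh9. Distal territory is the sequence more than 2 kb from every chosen gene end, within 50 kb of the gene's own and nearest to it. It can hold start sites that lie away from the chosen ends. Iqgap1, Rbpj, Cdkn1a, Mef2a and Hdac4, for example, had no covered base in their windows in any of the 4 libraries, so any promoter of theirs away from those ends was counted as distal. Near Cd44, the hyaluronan receptor (chr2:102811141–102901669), distal peaks covered 29.5 ± 3.55 against 4.75 ± 0.082 kb, adjusted p = 0.00428. Near the cytoskeletal genes Myh9, Iqgap1 and Myo10 they covered 40.6 ± 3.75 against 17.9 ± 1.2, 31.6 ± 3.99 against 8.94 ± 0.209 and 20.4 ± 2.2 against 2.03 ± 0.989 kb. The territory of Runx1, a transcription factor gene near empty in FISC, held 19.1 ± 2.93 against 0.57 ± 0.00707 kb. The growth factor gene Csf1 (22.9 ± 2.72 against 3.71 ± 0.0537 kb), the integrin gene Itgb6 (28.6 ± 1.32 against 6.69 ± 0.0813 kb), the chromatin gene Bahcc1 (28.6 ± 1.97 against 7.31 ± 2.41 kb), the sialyltransferase gene St3gal1 (25.2 ± 3.47 against 4.14 ± 0.0106 kb) and the adaptor gene Shb (21.1 ± 2.78 against 3.11 ± 0.245 kb) rose as well, with limma adjusted p-values between 0.00424 and 0.00539 for the 10.

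The longest losses lay near Clmn, an actin-binding membrane protein gene (chr12:104763114–104865082; 5.13 ± 1.58 against 25.7 ± 1.76 kb, adjusted p = 0.00424), and the protease gene Htra3 (8.44 ± 1.49 against 22.8 ± 0.411 kb). The Hedgehog effector Gli2 (1.05 ± 0.13 against 11.6 ± 1.14 kb) and Tgfbr3, a coreceptor of transforming growth factor beta and a member of the quiescence list (0.911 ± 0.203 against 11 ± 0.253 kb), lost most of their distal coverage. Prkcq, a protein kinase C (1.49 ± 0.0665 against 13 ± 0.365 kb), Prex1, an activator of Rac (2.76 ± 0.913 against 13.9 ± 0.182 kb), the matrix gene Prelp (2.32 ± 0.822 against 13.1 ± 0.709 kb), the mitochondrial ribosomal gene Mrpl23 (2.29 ± 0.622 against 12.3 ± 0.197 kb) and Gpx3 (0.89 ± 0.787 against 10.3 ± 0.794 kb) fell too. Cyria, an inhibitor of Rac, fell (7.7 ± 1.98 against 17.3 ± 1.35 kb, adjusted p = 0.0127), a call lost without FISC replicate 2 (limma adjusted p = 0.0591).

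Of 8774 genes with distal coverage, 3955 rose in ASC and 866 fell. The median was +0.526 kb and stayed positive, +0.195 kb, after division by total covered length, where 3301 rose and 1717 fell and the share of rises among calls went from 82.0 to 65.8%. Of the rises 3250 held on both scales, and so did 865 of the falls, which division can only deepen. At equal covered length the split turned, with 1296 rises and 2232 falls. Of the 3955 rises as covered, 1273 held there and 201 reversed to a fall, and 810 of the 866 falls held. Conditions did not overlap in 81.3% of genes (5628 higher and 1501 lower), against 33.3% for 1 gene with exchangeable libraries. As in windows, list length enters this share. Rises and falls were 2642 and 528 without ASC replicate 1, 2003 and 751 without ASC replicate 2, 2605 and 378 without FISC replicate 1, and 2556 and 407 without FISC replicate 2.

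In distal territory, Calcr and Hey1 passed the test among the fixed regulators as covered, and Pax7, Spry1 and Myog passed on other scales. Near Pax7 it held 19.4 ± 3.74 against 17.9 ± 1.37 kb, adjusted p = 0.645, with the difference reversed to a fall that passed when scaled (−7.20 kb, limma adjusted p = 0.0133) and at equal covered length (−8.60 kb, 0.0117). Near Myf5 it held 2.28 ± 0.0544 against 1.99 ± 0.153 kb, adjusted p = 0.328. Myod1 had 6.62 ± 0.53 against 5.35 ± 0.92 kb, adjusted p = 0.199. Spry1 had 7.92 ± 0.798 against 10.3 ± 0.851 kb, adjusted p = 0.108, and passed as a fall when scaled (−6.69 kb, 0.00585) and at equal covered length (−6.54 kb, 0.0103). Myog had 0.68 ± 0.609 against 0.644 ± 0.206 kb, adjusted p = 0.936, and reversed to a fall that passed at equal covered length (−0.645 kb, 0.0212). Near Calcr coverage fell (0.476 ± 0.376 against 3.22 ± 0.389 kb, adjusted p = 0.00614), and near Hey1 it fell as well (0.643 ± 0.436 against 2.51 ± 0.355 kb, adjusted p = 0.0148). Cdkn1c was not among the genes with enough distal coverage to be tested.

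In distal territory, camera set inflammatory and quiescence genes apart as covered, and at the preset correlation only the inflammatory call was kept at equal covered length. For inflammatory mediators 14 rose and 0 fell of 16 (15 and 0 adjusted over the list alone, 13 and 0 scaled; adjusted p = 0.00979), with means of 6.84 and 1.74 kb and an adjusted p = 0.980 with an estimated correlation. With lists cut to equal covered length 6 of 12 rose and 1 fell (camera adjusted p = 0.0247; 0.968 with an estimated correlation). Territories of Ccl2 (12.5 ± 0.857 against 1.32 ± 0.143 kb), of Nfkbia, the inhibitor of NF-kB (10.9 ± 0.119 against 4.11 ± 0.322 kb), and of the cytokine gene Lif (14.8 ± 1.18 against 8.12 ± 0.0233 kb) rose. For quiescence genes 3 rose and 5 fell of 21 (3 and 5 adjusted over the list alone, 3 and 12 scaled; adjusted p = 0.00979), with means of 4.65 and 5.45 kb and an adjusted p = 0.980 with an estimated correlation. With lists cut to equal covered length 2 of 20 rose and 14 fell, but the camera call was lost (adjusted p = 0.0578). The forkhead gene Foxo1 fell (1.73 ± 0.807 against 6.88 ± 0.134 kb), while the Notch target Hes1 (6.35 ± 0.738 against 0.989 ± 0.187 kb) and the Wnt receptor gene Fzd7 (4.91 ± 0.895 against 0 ± 0 kb) rose. The calls for Nfkbia (limma adjusted p = 0.0505) and Lif (0.182) were lost without FISC replicate 1, and that for Lif without FISC replicate 2 (0.189).

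Satellite cell, Notch, myogenic and cell cycle lists were not set apart distally. For satellite cell identity 7 rose and 2 fell of 16 (7 and 2 adjusted over the list alone, 4 and 7 scaled; adjusted p = 0.807). Met (19.7 ± 4.41 against 4.46 ± 0.192 kb) and Itga7 (8.39 ± 0.688 against 3.52 ± 0.291 kb) rose, Chrdl2 fell (2.36 ± 0.508 against 10.1 ± 1.14 kb), and the dystroglycan gene Dag1 had 12.3 ± 3.77 against 17.6 ± 1.64 kb, adjusted p = 0.137. For the Notch pathway 5 rose and 3 fell of 14 (5 and 3 adjusted over the list alone, 5 and 6 scaled; adjusted p = 0.751). The ligand Dll1 (11.5 ± 0.888 against 2.01 ± 0.54 kb) and the effector Rbpj (13.1 ± 1.38 against 5.66 ± 0.501 kb) rose. For myogenic genes 12 rose and 2 fell of 23 (12 and 2 adjusted over the list alone, 11 and 4 scaled; adjusted p = 0.829). The cell cycle inhibitor Cdkn1a (9.95 ± 0.808 against 3.73 ± 0.778 kb) and the factor Mef2a (7.83 ± 0.907 against 2.16 ± 0.0453 kb) rose. For cell cycle genes 9 rose and 0 fell of 18 (9 and 0 adjusted over the list alone, 9 and 2 scaled; adjusted p = 0.751). Cdk6 (14.1 ± 2.86 against 1.69 ± 0.0255 kb) and E2f2 (8.61 ± 0.426 against 3.16 ± 0.119 kb) rose. The calls for Itga7, Rbpj and Cdkn1a were lost without FISC replicate 1 (limma adjusted p = 0.0543, 0.0715 and 0.0590), and that for Rbpj without FISC replicate 2 (0.103).

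Stress and metabolic lists were not set apart from other genes in distal territory. For immediate early genes 10 rose and 3 fell of 24 (10 and 3 adjusted over the list alone, 9 and 10 scaled; adjusted p = 0.92). Ier5 (17.2 ± 0.36 against 7.03 ± 1.66 kb) and Fos (18.7 ± 3.35 against 9.55 ± 0.703 kb) rose, Fos reversing when territories were cut at 20 kb. For heat shock genes 3 rose and 0 fell of 9 (3 and 0 adjusted over the list alone, 3 and 1 scaled; adjusted p = 0.751), Hsp90aa1 rising (7.59 ± 0.268 against 1.63 ± 0.0325 kb) and the cochaperone Bag3 at 7.67 ± 1.77 against 4.51 ± 0.218 kb, adjusted p = 0.0605. For ribosome biogenesis 1 rose and 0 fell of 6 (1 and 0 adjusted over the list alone, 1 and 0 scaled; adjusted p = 0.763). Polr1a, a subunit of RNA polymerase I, rose (1.01 ± 0.197 against 0.10 ± 0.141 kb) but reversed with territories of 100 kb, and Nop2 had 6.7 ± 0.417 against 5.28 ± 1.24 kb, adjusted p = 0.203. For glycolysis 7 rose and 0 fell of 14 (7 and 0 adjusted over the list alone, 5 and 2 scaled; adjusted p = 0.751). There were rises at the glucose transporter gene Slc2a1 (8.09 ± 0.435 against 0.75 ± 0.366 kb) and the hexokinase gene Hk2 (6.64 ± 2.69 against 0.116 ± 0.164 kb). For oxidative phosphorylation 1 rose and 1 fell of 4 (1 and 1 adjusted over the list alone, 1 and 2 scaled; adjusted p = 0.807). Sdhb rose (3.41 ± 0.0983 against 0.11 ± 0.155 kb) and Cox4i1 fell (0 ± 0 against 1.46 ± 0.177 kb). Without FISC replicate 1 the calls for Ier5, Fos and Polr1a were lost (limma adjusted p = 0.131, 0.156 and 0.0611), and without FISC replicate 2 those for Ier5 and Fos (0.0602 and 0.205).

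For extracellular matrix genes 13 rose and 6 fell of 28 (13 and 6 adjusted over the list alone, 11 and 9 scaled; adjusted p = 0.751). The collagen gene Col5a1 fell (11 ± 2.01 against 19.6 ± 0.274 kb) and Tnc, a tenascin of regenerating tissue, rose (10.7 ± 0.944 against 2.67 ± 0.19 kb). For the interferon response 2 rose and 0 fell of 7 (1 and 0 adjusted over the list alone, 2 and 2 scaled; adjusted p = 0.751). There were rises at Irf1 (14.8 ± 1.05 against 4.7 ± 0.19 kb) and Ifi35 (0.408 ± 0.165 against 0 ± 0 kb). For genes acting on H3K27 3 rose and 2 fell of 13 (3 and 1 adjusted over the list alone, 2 and 4 scaled; adjusted p = 0.743). The deacetylase gene Hdac4 rose (14.7 ± 1.12 against 6.92 ± 0.528 kb), reversing with territories of 100 kb, and the methyltransferase gene Ezh1 fell (0.282 ± 0.40 against 2.48 ± 0.099 kb). For Hox genes 3 rose and 0 fell of 11 (1 and 0 adjusted over the list alone, 1 and 3 scaled; adjusted p = 0.807). Hoxa11 (4.96 ± 0.0778 against 1.53 ± 0.0318 kb) and Hoxc11 (8.65 ± 0.433 against 6.16 ± 0.283 kb) rose, Hoxc11 reversing when scaled or at equal covered length. Without FISC replicate 1 the calls for Col5a1, Ifi35, Hdac4 and Hoxc11 were lost (limma adjusted p = 0.137, 0.124, 0.101 and 0.276), as without FISC replicate 2 (0.153, 0.125, 0.14 and 0.369). Scaled mean differences turned negative for matrix, H3K27, Hox, immediate early, Notch, ribosome biogenesis and satellite cell lists.

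Near genes of other cell types no list was set apart from other genes in distal territory, and 45.1% of all 8774 genes tested rose. For fibro-adipogenic and fibroblast genes 4 rose and 2 fell of 10 (5 and 2 adjusted over the list alone, 4 and 2 scaled; adjusted p = 0.932). There were rises near the matrix gene Smoc2 (4.26 ± 0.103 against 0 ± 0 kb) and the decorin gene Dcn (4.63 ± 0.202 against 0.427 ± 0.144 kb). For endothelial genes 5 rose and 1 fell of 11 (5 and 1 adjusted over the list alone, 4 and 2 scaled; adjusted p = 0.829). There were rises near the junction genes Cldn5 (9.22 ± 1.78 against 2.05 ± 0.206 kb) and Cdh5 (3.65 ± 0.369 against 0.295 ± 0.417 kb). For neuronal genes 5 rose and 0 fell of 7 (5 and 0 adjusted over the list alone, 5 and 1 scaled; adjusted p = 0.742). The neurofilament gene Nefl (5.24 ± 0.68 against 0.123 ± 0.174 kb), the glutamate decarboxylase genes Gad2 (3.62 ± 0.127 against 0 ± 0 kb) and Gad1 (2.25 ± 0.209 against 0 ± 0 kb), and the synaptotagmin gene Syt1 (2.62 ± 0.675 against 0.106 ± 0.15 kb) rose. For liver genes 2 rose and 1 fell of 5 (2 and 1 adjusted over the list alone, 2 and 1 scaled; adjusted p = 0.974). The lipid carrier Apob rose (1.97 ± 0.307 against 0 ± 0 kb) and the thyroxine carrier Ttr fell (0.218 ± 0.0247 against 1.41 ± 0.105 kb). For smooth muscle and pericyte genes 4 rose and 3 fell of 9 (4 and 3 adjusted over the list alone, 2 and 3 scaled; adjusted p = 0.743), Cspg4 (4.48 ± 1.05 against 1.51 ± 0.223 kb) and Acta2 (2.84 ± 0.0396 against 1.22 ± 0.305 kb) rising. For Schwann and tendon genes 5 rose and 0 fell of 9 (7 and 1 adjusted over the list alone, 4 and 1 scaled; adjusted p = 0.751). Scx (4.77 ± 0.525 against 1.97 ± 0.177 kb) and the myelin gene Mbp (5.85 ± 0.0665 against 3.82 ± 0.0106 kb) rose, Mbp reversing when scaled or at equal covered length.

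For myeloid genes 3 rose and 0 fell of 7 (2 and 0 adjusted over the list alone, 2 and 0 scaled; adjusted p = 0.807). The lysosomal gene Laptm5 rose (2.26 ± 0.728 against 0 ± 0 kb), and Fcgr3 had 1.57 ± 1.02 against 0.276 ± 0.107 kb, adjusted p = 0.107, reversing at equal covered length. For lymphoid genes 0 rose and 1 fell of 3 (0 and 1 adjusted over the list alone, 0 and 2 scaled; adjusted p = 0.27). The B-cell factor Pax5 fell (0 ± 0 against 0.299 ± 0.0658 kb, adjusted p = 0.0199), reversing with territories of 100 kb, and Cd2 had 1.46 ± 0.622 against 2.61 ± 0.441 kb, adjusted p = 0.09. The call for Pax5 was lost without ASC replicate 1 or 2 (limma adjusted p = 0.208 and 0.215), that for Acta2 without FISC replicate 1 (0.0803), and that for Mbp without FISC replicate 1 or 2 (0.178 and 0.176).

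Of 69 distal calls for named genes, 4 were lost after division by total covered length: Hoxc11 and Mbp, whose sign turned, Lif (+1.7 kb, limma adjusted p = 0.0617) and Acta2 (+0.776 kb, 0.101). Lists of equal covered length lost 9. These were Slc2a1 (+1.03 kb, 0.56), Hk2 (+1.42 kb, 0.0523), Nefl (+2.14 kb, 0.203), Ier5 (+5.21 kb, 0.151), Sdhb (+0.947 kb, 0.0804), Nfkbia (+2.20 kb, 0.0932), Lif (+4.13 kb, 0.0869), Hoxc11 (−0.324 kb, 0.599) and Mbp (−1.04 kb, 0.0973). Polr1a, Ifi35, Laptm5 and Apob had too little coverage there to be tested.

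Changes at start sites and in distal territory went together more often than independent draws would give. Among 6641 genes tested in both, 1170 rose in both, where 849 would be drawn if the calls were independent, and 121 fell in both (30.2 if independent). Opposite calls were rarer: 65 genes rose in the window and fell distally (187 if independent), and 41 did the reverse (137). Gpx3 fell in both places, E2f2, Met, Itga7 and Ccl2 rose in both, and Calcr fell in both. Both measures came from the same libraries, so any difference in list length between libraries enters each of them. Distal territory also begins where the window ends, so a peak that crosses the 2 kb edge adds to both. How much of the excess over independence this gives was not tested.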

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

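Equal covered length, both gene ends, unshared windows and scaling with the block were chosen after the results were seen; the other settings were fixed before. At equal covered length, regions specific to ASC and FISC became 1583 and 13080, genes with a window peak in a single condition 126 and 1675, window rises and falls 2041 and 1528, and distal rises and falls 1296 and 2232. By construction that cut removes more of the longer ASC lists. It moved the ASC minus FISC share of peaks to 20.9 points in windows and −4.73 points between genes, and the window share of length to 3.68 points. Lists cut to equal peak number gave 3170 window rises and 508 falls, and 3652 distal rises and 1041 falls. Stricter peaks gave 8696 ASC-specific regions (fold enrichment) and 3045 (q) or 1601 (fold enrichment) FISC-specific ones, 268 window falls and 376 distal falls (both fold enrichment). Division by total covered length gave 1114 window rises, 5073 window falls and 1717 distal falls, and with the replicate block 1127, 5071 and 1707. The block alone gave 3047 and 418 in windows and 4107 and 921 in distal territory. Among named genes the block added 3 window calls, at Hey1, Ier3 and Uqcrfs1 (limma adjusted p = 0.0278, 0.0379 and 0.0214), and lost 0. Distally it added 2 and lost 1. Windows of 1 kb gave 1935 rises and 219 falls, and unshared windows 2186 rises. Among named genes, windows of 1 kb lost 16 calls and added 1. The log scale lost 6 window calls and added 1, and the cut-off on fold enrichment lost 5 and added 1. Distally a limit of 20 kb lost 6 calls and added 1.

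Leaving out each library gave 15758 to 26950 ASC-specific and 5702 to 13073 FISC-specific regions, 295 to 477 genes with a window peak in FISC only, 841 to 3256 window rises, 55 to 334 window falls, 2003 to 2642 distal rises and 378 to 751 distal falls. With a lone library in a condition, that condition was assumed to vary like the other. Lists above other genes in windows numbered 0 with an estimated correlation, 12 with fry, 4 scaled and 2 with the block, and lists below numbered 0 with an estimated correlation and 0 with fry. Distally, lists above were 0 with an estimated correlation and 7 with fry, and lists below 0 with an estimated correlation, 0 with fry and 0 at equal covered length. fry tests movement of a set by itself, so a general gain enters it.

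Named genes are given here as reversed where the difference passed before or after the turn. When scaled, with or without the block, these were Hspe1 −0.274, Hspd1 −0.328, Eno1 −0.334, Suz12 −0.0724, Eed −0.218, Scx −0.171 and Spry1 −1.25 kb in windows, and Hoxc11 −0.803, Mbp −0.0822 and Pax7 −7.20 kb distally. With lists of equal covered length they were Rrs1 −0.0045 and Spi1 −0.818 kb in windows, and Hoxc11 −0.324, Fcgr3 −0.276, Mbp −1.04, Pax7 −8.60 and Myog −0.645 kb distally. A 20 kb limit turned Fos to −0.316 kb, and a 100 kb limit turned Polr1a to −0.290, Hdac4 to −1.16 and Pax5 to 0.0155 kb. Values of Ier3, Uqcrfs1 and Spi1 windows and of Nop2, Myf5, Myod1 and Myog territory turned when scaled, and those of Lfng, Fcgr3, Myod1 and Spry1 windows at equal covered length, with no pass on either scale. The cause of these turns was not tested. All contigs gave the same values as the main run. Motifs with their alternatives and the 5'-most start site were not run.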

Other observations

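The gene families and every test in this part were chosen after the result was seen. Windows of replication-dependent histone genes widened from 1.12 ± 0.06 kb in FISC to 2.73 ± 0.13 kb in ASC (n = 2), with 47 rises and 0 falls among 57 genes (50 and 0 adjusted over the list alone; 35 and 6 scaled; camera adjusted p = 1.1e-11, adjusted p = 0.964 with an estimated correlation). The large cluster on chr13 carried this: its 47 members went from 0.868 ± 0.04 to 2.69 ± 0.15 kb, with 35 rises and 0 falls when scaled. The 10 members on chr3 went from 2.29 ± 0.15 to 2.93 ± 0.07 kb and had 0 rises and 6 falls when scaled. The 57 windows form 27 separate blocks of touching windows. The counts and the camera p at the preset correlation therefore take some bases more than once. Histone genes share sequence with near-identical copies, so each gene's own value is uncertain. At equal covered length the median difference was 1.76 kb on chr13 and 0.218 kb on chr3, beside 0.191 kb for all genes.

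Cytosolic ribosomal protein genes had 31 rises and 0 falls among 87 windows (40 and 0 adjusted over the list alone; camera adjusted p = 0.0403, adjusted p = 0.980 with an estimated correlation), a direction that turned to 0 and 35 when scaled and was 22 and 1 of 86 at equal covered length. Potassium channel genes lay below other genes, with 8 rises and 5 falls among 34 (camera adjusted p = 0.0178, adjusted p = 0.964 with an estimated correlation). When scaled they had 4 and 16 and no call (0.834), and at equal covered length 2 and 13 of 30. Kinesin genes, the motors of spindles and transport, had 15 rises and 0 falls among 31 windows and 13 and 0 among 17 distal territories (camera adjusted p = 0.276 and 0.232, neither called). When scaled the windows split into 7 and 9, and the territories had 11 and 0. Distal territory of claudin genes, which seal epithelial junctions, was 3.22 kb in ASC and 0.538 in FISC (10 rises and 0 falls of 13; 10 and 0 scaled; 5 and 1 of 9 at equal covered length), and that of axonemal dyneins 2.97 and 0.847 kb (8 and 0 of 10; 7 and 0 scaled; 2 and 0 of 7). Neither family was called apart from other genes, of which 45.1% rose (camera adjusted p = 0.232 and 0.818; 0.984 for both with an estimated correlation).

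The longer covered length in ASC was weighed against deeper ASC libraries and against stronger enrichment. If background follows depth, the estimate goes against deeper sequencing. The highest ASC to FISC ratio of background reads was 1.053, while ratios of covered length lay between 1.43 and 1.71. Whether background follows depth could not be checked, since the settings of the peak caller and the part of the inputs are not given. Background was inferred from fold and p at 65.4 to 83.5% of peaks, not counted from reads, and within ASC it rose with covered length (ratios 1.23 and 1.17). Stronger enrichment in ASC as the cause of every difference would leave few regions seen in FISC only, and 5301 were, against at most 645 for a mixed pair of libraries. Median fold enrichment, 5.45 ± 0.376 in ASC and 4.77 ± 0.283 in FISC, was higher in both ASC libraries. So was the highest fold, 52.4 ± 6.29 against 35.2 ± 0.637. Those values go with stronger enrichment, though fold depends on each library's depth and background. As the cause of the total, stronger enrichment and a true spread of acetylation cannot be told apart. Each could give the intergenic ratio of 2.013 beside 1.25 in windows.

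The wider histone windows were weighed against the shared windows of neighbouring genes, the longer covered length in ASC at all genes, and reads shared between near-identical copies. Rises lay in 21 of 27 separate blocks of touching windows (19 of 22 on chr13, 2 of 5 on chr3), so they were not a few windows counted many times; blocks of one cluster are not independent of each other. The longer covered length at all genes is argued against for the members in the large cluster on chr13, whose median stayed at +1.215 kb after division by total covered length, while for those outside the large cluster, on chr3, it cannot be told apart from a gain of their own: their median was −0.897 kb with 0 rises, but the blocks holding their 4 rises stayed above 0 in value (+0.527 and +0.104 kb). Reads shared between near-identical copies, with a correlation of residuals of 0.0872 within the family, cannot be told apart from a gain at each gene. The chr13 gain would fit a larger share of S-phase cells among ASC, as would the Tk1 and Rrm2 windows. The 10 chr3 members, replication-dependent histone genes too, do not add to that reading. As covered 4 of them rose and 0 fell, and when scaled 0 rose and 6 fell. At equal covered length their median difference was 0.218 kb, beside 0.191 kb for all genes. The share of S-phase cells was not tested, and counts of DNA content in the same cells could test it.

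The place of quiescence genes below other genes in windows in ASC, where 6 of 23 fell and 3 rose, was weighed against smooth muscle cells and pericytes among the FISC and against a change of scale between the lists. Smooth muscle cells and pericytes among the FISC cannot be told apart from a change in the stem cells. With them goes that 4 of the 6 tested marker windows fell and 0 rose. In distal territory 4 of 9 markers rose and 3 fell. That share of rises is near the 45.1% of all genes that rose there, so it decides nothing. Windows of Rgs5, Kcnj8, Cnn1 and Higd1b had no covered base in any library, but an uncovered window does not mark a silent gene. The fall of Calcr, a gene of satellite cells, points to a change in the stem cells too. A change of scale alone was taken to place the list below other genes on neither of the other scales. At the preset correlation camera placed it there at equal covered length (adjusted p = 0.02957), which goes against a change of scale. It did so when scaled too (0.00274), but division by the total lowers wide windows more than narrow ones. Windows of the list had 2.23 ± 0.0842 kb in FISC, beside 1.25 ± 0.0185 kb for all genes with a chosen end. The scaled call therefore decides nothing about scale. Such calls rest on the spread between genes, so the libraries still leave it open. With an estimated correlation both calls were lost (0.652 and 0.474). That loss decides nothing about scale, since the call as covered was lost there too. Sorting by a marker absent from mural cells could test the first of these.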
